A study of Mus musculus with 56 samples.

How the data were processed

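Single cells were profiled by RNA-seq (Bead-seq in the labels) from 3 pooled colon tumors of 1 mouse. Libraries carried 1 of 7 i7 and 1 of 8 i5 indexes, with 56 libraries in all, 8 per i7 index and 7 per i5 index. The deposited table gave TPM for 24410 Ensembl gene IDs in each library. Per the submitters' processing notes, bcl2fastq 1.8.4, RSEM 1.2.31, Bowtie2 2.2.9 and the mouse build GRCm38.p4 were used; their settings, the annotation release and any use of strand are not given in the sources used here. TPM keep no read depth, so depth was unknown, and an exact 0 was read only as listed at 0. The table held 0 genes of the mitochondrial chromosome, so transcripts that resemble them can be listed under nuclear copies. Columns were matched to samples by the index pair in their names, and all 56 matched.

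Gene symbols were taken from the GENCODE M21 gene names for GRCm38, which matched 24235 IDs, and 175 IDs had no symbol. Coordinates came from the same annotation.

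The labels named no groups, so the design held 1 group, and cells of 1 mouse were not treated as replicates. The design, written before the data were examined, took each of the 56 libraries as a cell. After the values were seen, 6 pairs of libraries with Pearson's r above 0.9 (log2(TPM + 1), genes at 1 TPM or more in 20% of libraries) were averaged as 1 cell each, which gave 50 cells. The count of paired libraries of 1 i7 index was set against 10000 random orders of the i7 indexes over libraries. All results had first been computed over the 56 libraries, and these were kept as an alternative. A gene was called seen in a cell at 1 TPM or more. Shares of cells have exact Clopper-Pearson intervals at 95%, which cover counting error only. Correlations across cells were Spearman's rho on log2(TPM + 1), with the mean over a list as its level. Lists were set against 10000 random lists of the same size, matched to the members in 50 bins of mean expression among genes at 1 TPM or more in at least 3 cells, and called outside the band beyond the central 95% of them. These percentiles describe the cells at hand and are not p-values. Random lists were not matched on the correlation among members, so the band may be too narrow for lists whose members go together. Relations were repeated in cells of i7 indexes N704 to N707 and N708 to N710, and of i5 indexes N502 to N505 and N506 to N517.

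The genes named were fixed beforehand as the sort genes with Prox1, Cdkn1c, Mki67, Top2a and Apc, the 3 most frequent members of each of the 23 lists and members of note for its counts, the 10 highest and 10 lowest genes by rho with Prox1 and with the G2/M list among genes at 1 TPM or more in 20% of cells with the same sign of rho in both i7 groups, and the 10 genes with the highest mean and the largest SD. Not all frequent members are printed, and other list members were named after their values were seen. Clusters were made from the 1000 genes with the largest SD among genes seen in 20% of cells, 10 principal components and Ward linkage, with the number of clusters from 2 to 5 by the highest mean silhouette, and clusters under 5 cells were not described. A cluster was named only from markers fixed beforehand. No doublet caller was run, because cells were sorted singly and TPM carry no counts.

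Alternatives fixed beforehand were other detection thresholds (above 0 and 10 TPM), pseudocounts of 0.1 and 10, Pearson's r, partial rho given genes per cell, other filters on genes, TPM without ribosomal protein genes, leaving out the cell with few genes, leaving out each i5 index, and other cluster settings. Alternatives added after the data were seen were the 56 libraries as cells, TPM without ribosomal protein genes and Gm10925, leaving out the defensin-high cell, 20 further sets of random lists, and subtracting 0.0168% of the TPM of index-sharing libraries (the median share of Defa24). The list method was tested on simulated data, in which values of each gene were shuffled over cells, lists were set against 1000 random lists, and lists of 20 genes were planted to follow or oppose Prox1. It placed 20 of 20 planted lists above the band, 20 of 20 opposing lists below it and 0 of 20 unplanted lists outside it, over 11810 genes. Shuffling removed the correlation among genes, and planted genes were drawn from widely seen genes. The simulation therefore cannot tell how often lists of correlated genes leave the band without following or opposing Prox1. A single planted strength and a single list size were used, so it does not show how often weaker relations or shorter lists would be found. Clustering of shuffled cells with 200 genes raised 16-fold in 15 of them put 14 of the 15 in 1 cluster with 0 others. The planted difference was large and shuffling removed other structure, so this does not show how well weakly separated clusters are found. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.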

Results

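The data were single-cell RNA-seq libraries of epithelial cells sorted from colon tumors of a mouse, and the title of the series sets the transcription factor PROX1 against chemoresistance and quiescence of colon cancer stem cells. The tumors came from 1 male mouse that carried the Min allele of Apc, a truncating mutation that activates Wnt signaling and causes intestinal tumors. The mouse had received 2% dextran sulfate sodium, a polymer that injures the colonic epithelium, for 5 days from 10 weeks of age, and 3 tumors were pooled at 12 weeks. Living cells that carried EpCAM and CD24 and lacked the endothelial protein CD31 and the leukocyte protein CD45 were sorted, and libraries were made from cDNA in which a PCR of 32 cycles had found Lgr5, the intestinal stem cell receptor gene. There were 56 libraries in 1 group, with no group of cells named in the labels, so all relations below are described across cells of 1 mouse, with no test and no p-value. Values were TPM, which keep no depth, so the number of reads behind each value is unknown.

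The 56 libraries did not hold 56 separate profiles. In 6 pairs, Pearson's r of log2(TPM + 1) was 0.957 to 0.992, whereas the next highest r among the 1540 pairs of libraries was 0.782 and the median was 0.590. No pair of columns was identical. Each of the 6 pairs held at least 1 library with the i7 index N709, and all 8 libraries with that index were in a pair. Because TPM hold no counts, agreement within sampling noise could not be tested; each pair was averaged and counted as 1 cell, which left 50 cells.

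**Figure D1:**
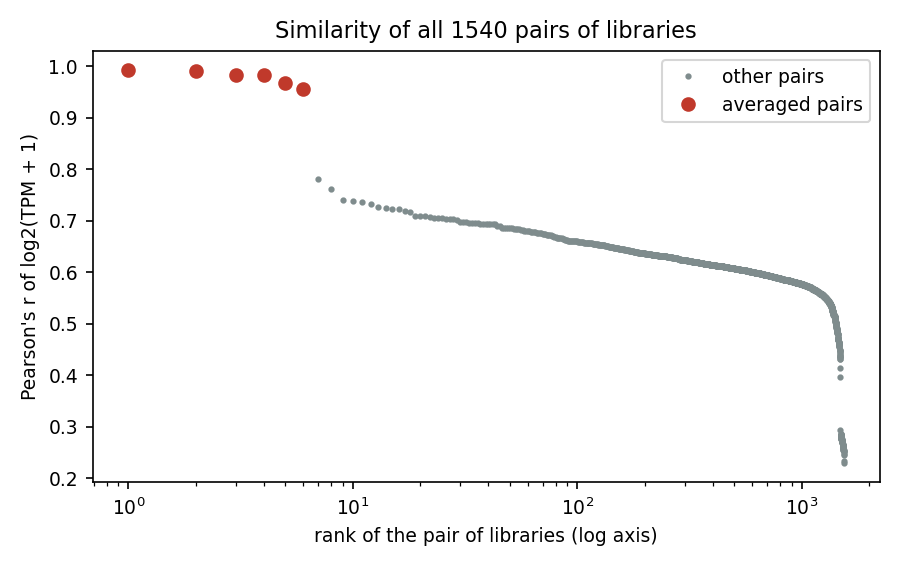
Pearson's r of log2(TPM + 1) for all 1540 pairs of libraries, ranked from the highest (log axis). The 6 averaged pairs sit at 0.957 to 0.992 and the next pair at 0.782.

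A median of 5903 genes per cell reached 1 TPM, with a range of 1316 to 7234. The largest share of TPM belonged to Gm10925, annotated as an unprocessed pseudogene on chromosome 1 (24613974 to 24614651, minus strand, GRCm38), which took a median of 8.82% of TPM per cell and ranged from 1.12% to 85.1%. The annotated Gm10925 transcript matched the mitochondrial gene mt-Atp6, which encodes a subunit of ATP synthase, at all 678 bases compared, and the table held 0 genes of the mitochondrial chromosome. The cell at 85.1% was also the one with 1316 genes. Next in mean log2(TPM + 1) came Actg1, Rpl14-ps1, Rps2, Ubb, Eef1a1, Rplp1, Rps15a-ps6, Rpl41 and Ifitm3, of which the ribosomal entries are uncertain because reads of ribosomal protein genes and their processed pseudogenes are hard to separate. The genes with the largest SD across cells were the histone genes Hist1h2ap (4.76 on the log2 scale) and Hist1h4i (4.11), the cornified envelope gene Sprr2a3 (4.75), the matrix gene Mgp (4.29), the antimicrobial lectin gene Reg3g (4.24), the metallothionein gene Mt3 (4.19), the heat shock gene Hspb1 (4.18) and Rnf186 (4.09), along with the microRNA entries Mir3082, which overlaps Jmjd8, Stub1 and Gm26694, and Mir678, which overlaps Prmt2, so that reads of those genes are not excluded.

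Both sorted surface proteins had their gene expressed in every cell, and the 2 excluded ones did not reach the threshold in any. Epcam was at 1 TPM or more in 50 of 50 cells (95% exact binomial interval 92.9% to 100%), with a median of 340 TPM and a range of 14.4 to 769. Cd24a was also at 1 TPM or more in 50 of 50 cells, with a median of 674 TPM. Pecam1, which encodes CD31, and Ptprc, which encodes CD45, reached 1 TPM in 0 of 50 cells (interval up to 7.11%). Lgr5 (ENSMUSG00000020140, chromosome 10, 115450311 to 115587780, minus strand, GRCm38) reached 1 TPM in 38 of 50 cells (76%, interval 61.8% to 86.9%), was above 0 in 49, and stayed low, with a median of 2.18 TPM and a maximum of 16.2. All such intervals cover counting error only. Apc was at 1 TPM or more in 30 cells, with a median of 1.45 TPM.

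Epithelial and Wnt target genes were widespread. Of 12 epithelial genes, a median of 10 per cell reached 1 TPM, and Krt8, Krt18 and Cldn3 did so in all 50 cells, whereas the intestinal homeobox gene Cdx2 did so in 2 and Cdx1 in 19. Of 15 Wnt target genes, a median of 10 per cell reached 1 TPM. The secreted Wnt inhibitors Wif1 and Notum and the feedback inhibitor Nkd1 were each seen in 47 cells, Rnf43 in 45 and Axin2 in 39. Of 15 stem cell genes, a median of 8.5 per cell reached 1 TPM. Prom1 led with 47 cells, followed by Sox9 and Smoc2 with 43 each, and Ascl2 was seen in 22. Olfm4, a stem cell marker of the small intestine, reached 1 TPM in 0 cells.

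Most G2/M genes were seen in a minority of cells, whereas some S phase genes were seen in most. The G2/M list of 30 genes had a median of 5 members per cell, with a range of 0 to 30, and 10 of 50 cells (20%, interval 10.0% to 33.7%) held at least 15 of them. Mki67 reached 1 TPM in 14 cells (28%, interval 16.2% to 42.5%) and Top2a in 18 (36%, interval 22.9% to 50.8%). Kif11, Cks2 and Plk1 were the exceptions in this list, seen in 48, 41 and 29 cells at medians of 5.62, 58.2 and 3.05 TPM. The S phase list of 22 genes had a median of 7 members per cell, with a range of 2 to 22. The replication factor genes Pcna, Mcm7 and Gins2 led with 47, 42 and 41 cells. Of 13 slow-cycling and reserve genes, a median of 8 per cell reached 1 TPM. Btg1 was seen in 49 cells, Btg2 in 48, Ndrg1 in 44 and the cell cycle inhibitor gene Cdkn1a in 43. Cdkn1c, which encodes the inhibitor p57, was seen in 17 cells, Hopx in 19 and Tert in 3.

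Most markers of mature and non-epithelial cells were seen in fewer than 25 of 50 cells or in none. Of 11 colonocyte genes, 7 reached 1 TPM in no cell, among them Car4, Aqp8, Slc26a3 and Krt20, and the exception was Car1, seen in 44 cells at a median of 3.27 TPM. Among 9 goblet cell genes, 1 reached 1 TPM in no cell, and Agr2 was seen in 25 cells, Spink4 in 8 and Muc2 in 1. Of 16 enteroendocrine genes, 7 reached 1 TPM in no cell, including Chga and Neurod1, yet Fev did so in 50 cells at a median of 36.3 TPM and Isl1 in 30. Of 13 tuft cell genes, 7 reached 1 TPM in no cell, including Pou2f3 and Trpm5, yet Avil did so in 46. The 12 immune, 6 endothelial and 7 fibroblast genes had 7, 4 and 5 members at 1 TPM in no cell, with Csf1r (21 cells), Vwf (5 cells) and Pdgfra (25 cells) as their most frequent. Fev, Car1, Kif11 and Pdgfra lay at the 98th, 97th, 96th and 96th percentile for the number of cells among genes of like mean expression, so their values were spread evenly over cells for their level. In the Paneth and deep crypt secretory list, 0 of 7 genes went unseen. The protease gene Mmp7 was seen in 48 cells at a median of 445 TPM, and the antimicrobial genes Lyz1 and Defa24 in 24 and 22, of which some values lie in libraries that share an index with a defensin-high library, as described at the end.

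Immediate early genes, which tissue dissociation can induce, were high in nearly all cells. Junb, Egr1 and Ier2 reached 1 TPM in all 50 cells, with medians of 1795, 1521 and 4766 TPM, and a median of 10 of the 12 dissociation response genes was seen per cell. Of 9 regenerative or fetal-like genes, a median of 4 was seen, with S100a6 in 50 cells, Clu in 43, Anxa1 in 32 and Ly6a in 12. Of 9 Notch pathway genes, a median of 2 was seen, with Hes1 in 44 cells. Oxidative phosphorylation, glycolysis, ribosome biogenesis and housekeeping lists had medians of 12 of 12, 11 of 12, 9 of 12 and 8 of 8 members per cell, with Atp5b, Gapdh and Actb in 50 cells each and Npm1 in 49. Of 7 hypoxia genes, a median of 2 was seen, led by Egln3 in 28 cells. Among 10 drug handling genes, Gstp1 was seen in 49 cells, Ercc1 in 35 and Abcc1 in 27, whereas the efflux transporter genes Abcb1a and Abcg2 reached 1 TPM in 0 cells.

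The first relation asked how Prox1, named in the title, went with genes of the cell cycle. Prox1 (ENSMUSG00000010175, chromosome 1, 190118035 to 190170714, minus strand, GRCm38) reached 1 TPM in 41 of 50 cells (82%, interval 68.6% to 91.4%), with a median of 14.7 TPM and a maximum of 66.8. Prox1 was lower in cells with more S phase expression. Spearman's rho between log2(TPM + 1) of Prox1 and the mean of the S phase list was -0.44 (50 cells), at percentile 0.01 among 10000 random lists of like expression, whose rho averaged 0.07 with an SD of 0.16. Pearson's r was -0.47, and it was -0.43 without the 2 cells farthest from the median of the list. Spearman's rho was -0.50 in the 32 cells of i7 indexes N704 to N707 and -0.30 in the 18 cells of N708 to N710. It was -0.54 among the 26 cells with a library of i5 indexes N502 to N505 and -0.32 among the 27 with a library of N506 to N517, as 3 averaged pairs had a library in each. All 22 members of the list had a negative rho with Prox1, from -0.57 for the chromatin remodeler gene Hells to -0.09 for Gins2, with Mcm5 at -0.53, Tyms at -0.495 and Pcna at -0.46. The members went together across cells (rho 0.41 to 0.77 with the mean of the list), so their signs are not separate observations. No p-value is given for any correlation, because cells of 1 mouse are not independent replicates.

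**Figure D2:**
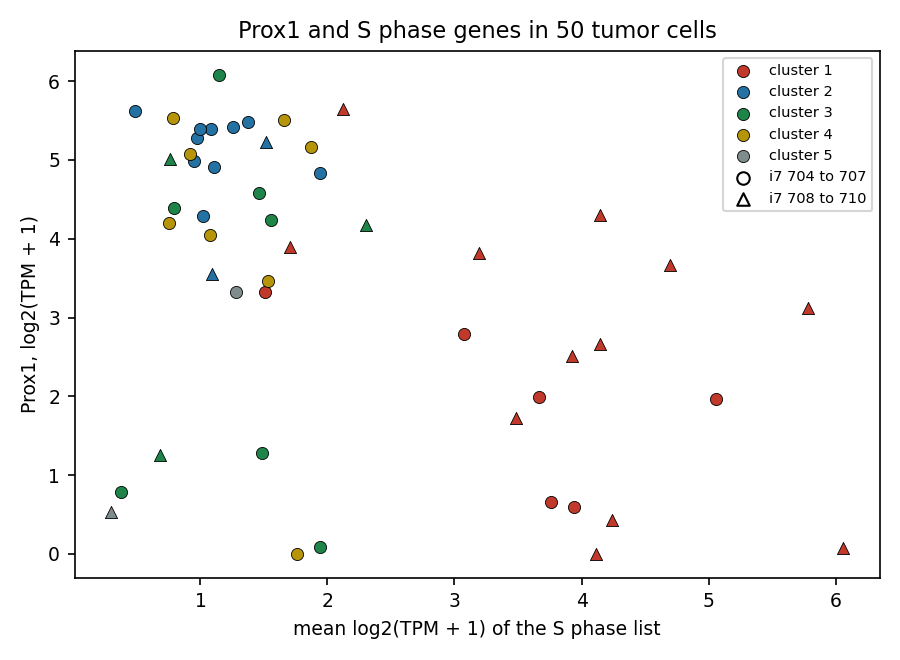
Prox1 as log2(TPM + 1) against the mean log2(TPM + 1) of the S phase list, with 1 point per cell (50 cells), colored by cluster and shaped by i7 index. Spearman's rho was -0.44 over all cells, and the cells of cluster 1 lie to the right.

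With the G2/M list the relation of Prox1 was weaker and did not hold in every index group or cluster. Spearman's rho was -0.24, at percentile 1.17 among random lists, with Pearson's r of -0.27, and -0.24 for r without the 2 farthest cells. It was -0.30 in the cells of i7 indexes N704 to N707 and 0.11 in those of N708 to N710, and it was -0.37 and 0.01 in the i5 groups. It was not negative on either side of the S phase-like cluster described further on, at 0.01 within it and 0.07 outside it. It was 0.54 in the 10 cells of cluster 3, which include the defensin-high cell. Over all cells it lay below percentile 2.5 of random lists in 9 of 19 alternatives. Ranked among the rhos of 9166 genes with the G2/M list, Prox1 lay at percentile 3.57, inside the central 95%. Of the 30 members, 29 had a negative rho, with Tacc3 at -0.47, Anln at -0.40, Top2a at -0.11 and Mki67 at -0.14. Members of this list went together too, so their signs are not separate observations. In joint counts at 1 TPM, Prox1 was seen in 10 of 14 cells with Mki67 (71.4%, interval 41.9% to 91.6%) and in 31 of 36 without it (86.1%, interval 70.5% to 95.3%). It was seen in 15 of 18 cells with Top2a and in 26 of 32 without it. At 10 TPM, 4 of 11 cells with Mki67 had Prox1 (36.4%, interval 10.9% to 69.2%), against 26 of 39 without it (66.7%, interval 49.8% to 80.9%). These intervals overlap.

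Cdkn1c (ENSMUSG00000037664, chromosome 7, 143458339 to 143461050, minus strand, GRCm38) was read in the same way, as the gene of an inhibitor linked to slow cycling. It reached 1 TPM in 17 of 50 cells (34%, interval 21.2% to 48.8%), with a maximum of 577 TPM, and was listed at 0 in the others. Spearman's rho was -0.21 with the S phase list, at percentile 2.62 among random lists and so just inside the band, and -0.05 with the G2/M list, at percentile 32.4. Ranked among the rhos of 9166 genes with these lists, Cdkn1c lay at percentiles 4.15 and 20.1. Pearson's r was -0.13 and -0.08, and -0.07 and -0.14 without the 2 farthest cells. Within i7 indexes N704 to N707 and N708 to N710, rho with the S phase list was -0.18 and -0.21, and it was -0.26 within the S phase-like cluster and -0.28 outside it. Cdkn1c was seen in 5 of 14 cells with Mki67 and in 12 of 36 without it. Prox1 was seen in 15 of the 17 cells with Cdkn1c (88.2%, interval 63.6% to 98.5%) and in 26 of the 33 without it (78.8%, interval 61.1% to 91.0%). Prox1 and Cdkn1c overlap other annotated genes, Prox1os and Gm28172 for Prox1 and Gm44732 for Cdkn1c, and whether counting used strand is not given in the sources used here.

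Across the 23 gene lists, by the median of the rhos of their members, Wnt targets went with Prox1, and cycling and growth genes went against it. The median rho with Prox1 was 0.25 for the Wnt targets, above the central 95% of random lists, with Nkd1 at 0.62, Apcdd1 at 0.53, Znrf3 at 0.51, Notum at 0.42 and Axin2 at 0.37, whereas Ccnd1 was at -0.30. By the mean of the Wnt targets, however, rho with Prox1 was 0.35 at percentile 94.6, inside the band, and it was 0.56 and 0.10 in the i5 groups N502 to N505 and N506 to N517, 0.29 outside the S phase-like cluster and -0.21 in cluster 3. The dissociation response list also had a median above the central 95%, at 0.23 (Ier3 at 0.36, Atf3 at 0.34 and Junb at 0.29), but not with Pearson's r. Below the central 95% lay the S phase (median of rho -0.42), G2/M (-0.21), ribosome biogenesis (-0.21), oxidative phosphorylation (-0.12), epithelial (-0.14), colonocyte (-0.17, 4 members) and goblet (-0.28, 3 members) lists. Nop58 at -0.35 and Npm1 at -0.30 were among the ribosome biogenesis genes, and Atp5b at -0.37 among those of oxidative phosphorylation. The goblet, oxidative phosphorylation, colonocyte and epithelial lists lay below in 16, 15, 13 and 12 of 19 alternatives. In the epithelial list members went both ways, with Cldn3 at 0.41 and Cdx1 at -0.32, and its median turned to 0.166 with Pearson's r, as that of oxidative phosphorylation turned to 0.0774. The stem list had a median of -0.05, within the range of random lists, with Lgr5 at 0.21 and Cdca7 at -0.38, and the other 13 lists were within it too. Of 23 lists, 9 lay outside, and these lists are related to each other, so they do not count as separate findings.

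**Figure D3:**
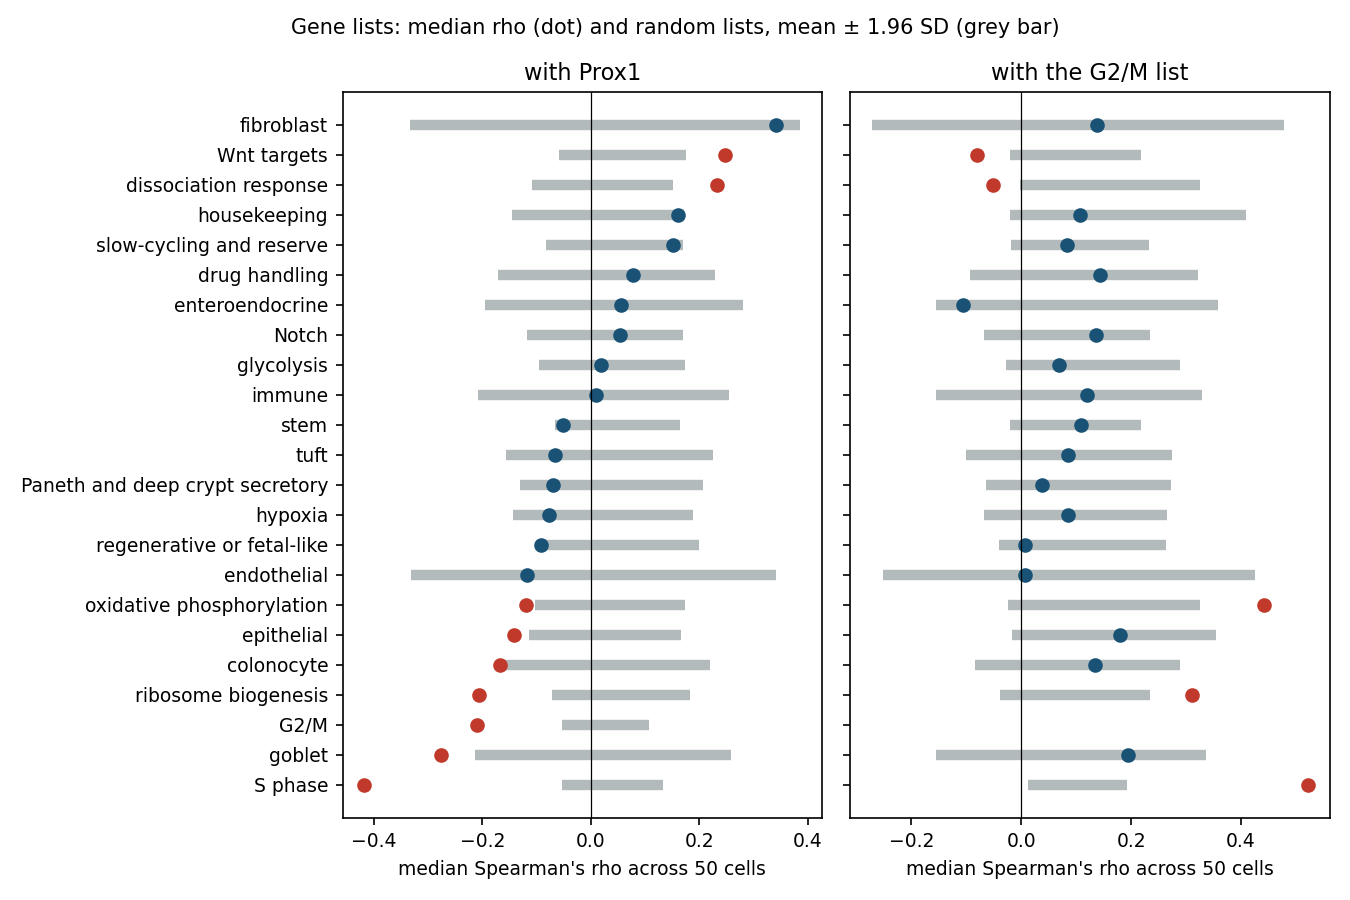
Median Spearman's rho of each gene list with Prox1 (left) and with the G2/M list (right) across 50 cells. Dots are list medians, red outside the central 95% of random lists, and grey bars span about 95% of those lists (from their mean and SD), with S phase and Wnt targets on opposite sides in both panels.

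Among single genes that had the same sign of rho in both i7 groups, the highest with Prox1 was Wnt10a, which encodes a Wnt ligand (rho 0.67, and 0.66 and 0.69 in the i7 groups). Ube2h (0.65), Esyt3 (0.64), Nkd1 (0.62), Msrb2 (0.62), Cdc42se1 (0.61), the T-box factor gene Tbx3 (0.61), Aspscr1 (0.60), Zswim4 (0.60) and Ptn (0.59) followed. Wnt10a reached 1 TPM in 14 cells. The lowest were Hells (-0.57), the mitochondrial creatine kinase gene Ckmt1 (-0.54), the lactate transporter gene Slc16a1 (-0.54), Fastkd2 (-0.53), Mcm5 (-0.53), Oit1 (-0.52), Gpx2-ps1 (-0.52), the brush border myosin gene Myo1a (-0.52), E130218I03Rik (-0.51) and the nucleotide metabolism gene Dut (-0.51). Gpx2-ps1 is a processed pseudogene by name, and its values were not separated from those of Gpx2.

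With the mean of the G2/M list, S phase, oxidative phosphorylation and ribosome biogenesis genes went up together. Their medians of rho were 0.52, 0.44 and 0.31, all above the central 95% of random lists, and every member of the 3 lists was positive, with Rrm1 at 0.66, Atp5b at 0.62 and Npm1 at 0.61. The Wnt targets (median -0.08) and the dissociation response list (-0.05) lay below it, the latter in 16 of 19 alternatives, with Nkd1 at -0.43 and Atf3 at -0.37. The stem list was within the range of random lists, at 0.11, with Cdca7 at 0.64 and Lgr5 at 0.08. The highest single genes outside the list were Ptma (0.76), Selenoh (0.76), the histone variant gene H2afz (0.75), Gm4737 (0.75), the tubulin gene Tuba1b (0.75), Rbm3 (0.75), Hmgn2 (0.74), Rps2 (0.72) and the kinetochore genes Spc24 and Spdl1 (0.71 each). The lowest were the NF-kB subunit gene Rela (-0.52), Gdf11 (-0.48), Npdc1 (-0.48), Ypel4 (-0.47), Krt18 (-0.46), Filip1l (-0.46), Cdh13 (-0.45), Atp6v1g1 (-0.45), Cuedc1 (-0.45) and Tnfrsf12a (-0.43). The number of genes per cell rose with the G2/M list (rho 0.58), whereas its rho with Prox1 was -0.09.

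Clustering separated a group of S phase-like cells, with weak boundaries. The highest mean silhouette over 2 to 5 clusters was 0.18, at 5 clusters of 18, 12, 10, 8 and 2 cells, and the smallest is not described. Cluster 1 (18 cells, 36%, interval 22.9% to 50.8%) was led by Hist1h2ap, Sprr2a3, Rnf186, Dut and Mcm5 and is called S phase-like from the markers fixed in advance, of which a median of 17.5 of 22 were seen per cell. It also held a median of 15.5 of 30 G2/M genes, against 5 over all cells, so it was not confined to S phase genes; 4 S phase and 7 G2/M genes were among the clustering genes. Clusters 2 (led by Mt3, Gdf11 and Vim), 3 (led by Gkn3 and Tspan1) and 4 (led by A930005H10Rik and Fam84a) had a median of 6 S phase genes per cell each, and none was given a name. Cluster 3 included the defensin-high cell described below, and rhos within cluster 3 were not repeated without that cell. Prox1, which was not among the clustering genes, had a median of 5.03 TPM in cluster 1 (range 0 to 49.2), 37 TPM in cluster 2 (10.8 to 48.4), 17.4 TPM in cluster 3 (0.06 to 66.8) and 25 TPM in cluster 4 (0 to 45.5). With the 56 libraries as cells, the median of Prox1 was 9.48 TPM in the S phase-like cluster and 19.3 TPM outside it, in place of 5.03 and 25.3 TPM. Lgr5 reached 1 TPM in 15 of 18, 7 of 12, 10 of 10 and 5 of 8 cells of these clusters, and Wnt10a in 1, 7, 2 and 4. Between Prox1 and the S phase list, rho was -0.42 within cluster 1, -0.07 in the 32 cells outside it, and -0.19, -0.08 and -0.19 in clusters 2, 3 and 4. The split itself used S phase genes, and the mean of the list spanned only 0.30 to 2.31 on the log2 scale outside cluster 1, against 1.51 to 6.06 within it, so the low rho outside cannot show that the relation was missing there. Cluster 1 held 6 of 32 cells of i7 indexes N704 to N707 (18.8%, interval 7.21% to 36.4%) and 12 of 18 of N708 to N710 (66.7%, interval 41% to 86.7%), so S phase-like cells were unequally spread over the indexes. The median of Prox1 went the other way, at 19.3 TPM in N704 to N707 and 9.24 TPM in N708 to N710.

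Libraries that shared an index were not more alike over all genes. The median rho across genes was 0.588 for pairs with the same i5 index, 0.593 for pairs with the same i7 index and 0.590 for pairs that shared neither, with the 6 averaged pairs left out. For 998 genes at 100 TPM or more in exactly 1 library, 50.2% of the values in libraries that shared an index with it were above 0, against 49.9% in those that did not. For 102 genes at 1000 TPM or more in exactly 1 library, these shares were 71.8% and 60.7%. The strongest such case was the library with i7 index N704 and i5 index N517, in which 24 defensin genes made up 76.0% of TPM, with Defa24 at 239134 TPM and Lyz1 at 44949 TPM, and Lgr5 at 1.37 TPM, Prox1 at 0.72 TPM and Epcam at 30.3 TPM. Defa24 was above 0 in 13 of 13 libraries that shared an index with it, at a median of 40.1 TPM, and in 8 of 42 that did not.

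**Figure D4:**
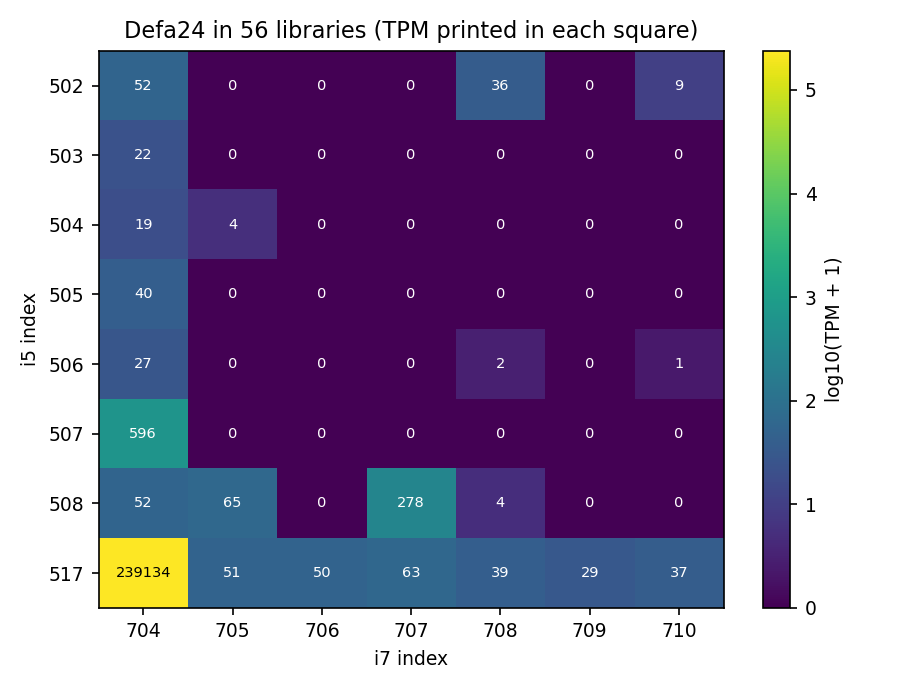
TPM of Defa24 in each of the 56 libraries, by i7 index (columns) and i5 index (rows), with color as log10(TPM + 1). The row and column of the library at 239134 TPM hold values above 0 throughout, and most other squares are 0.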

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

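The comparison with the 56 libraries, the rescaling without Gm10925, the defensin-high cell, the carry-over and further random lists were chosen after the data were seen. Prox1 and the mean of the S phase list kept a negative rho, below the 2.5th percentile of random lists, under all 19 alternatives (-0.52 to -0.36). By the median of the rhos of their members, the Wnt targets, G2/M and ribosome biogenesis lists kept their side of the band with Prox1 under all 19. The rho of Prox1 with the mean of the G2/M list stayed negative (-0.37 to -0.15). It lay below the 2.5th percentile under only 9 of 19, the 56 libraries being among the 10 others. That of Cdkn1c with the mean of the S phase list was below it under 7 of 19 (-0.30 to -0.11). With Pearson's r, the median with Prox1 turned to 0.166 for the epithelial and to 0.0774 for the oxidative phosphorylation list. The median of the dissociation response list with the G2/M list changed sign to 0.000231 and 0.0131 without i5 index N504 and N505. The cause was not tested. With 20 further sets of random lists, Cdkn1c with the S phase list (percentile 2.62) fell below the band in 4 and colonocyte genes with Prox1 (2.36) in 11. Subtracting the carry-over changed the count of cells for 29 of 277 list genes, by 5 or more for Lyz1 (24 to 18), Defa24 (22 to 15) and Defa17 (21 to 14), for Defa24 partly by construction, as its share set the amount. Genes per cell were 8209 above 0 TPM and 3540 at 10 TPM, and Lgr5 was seen in 98% and 14% of cells, by construction of the threshold. The S phase-like cluster held 15 to 21 cells under the alternatives except a pseudocount of 10, where it merged with others into 47 cells. With the 56 libraries as cells it held 18 libraries, beside clusters of 32, 2, 2 and 2. Of the 18, 14 were counted as shared with the main cluster, but the second library of an averaged pair could not be counted as shared. The difference between index-sharing and other libraries was 11.1 points at 1000 TPM in place of 0.303. Depth is unknown, so a gene listed at 0 may have been missed.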

Other observations

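The tests in this part were chosen after their results were seen, except the share of genes over all libraries, the rescaling without Gm10925, which was added after the data but before its result was seen, and repeats fixed beforehand as alternatives, among them the partial rho given genes per cell, whose use as a test came afterwards. Lgr5, by which the cells were picked, went with the other stem cell genes. Spearman's rho of Lgr5 with the mean of the 13 other stem genes was 0.47 (50 cells), at percentile 99.98 among random lists, with Pearson's r of 0.49, or 0.41 without the 2 farthest cells. It was 0.43 and 0.55 in i7 indexes N704 to N707 and N708 to N710, 0.28 and 0.50 in the i5 groups, and 0.49 outside the S phase-like cluster. With the S phase list rho was 0.03, with the Wnt targets -0.09 and with the G2/M list 0.08, which was -0.20 within the S phase-like cluster, 0.33 outside it and 0.67 in cluster 3. Prox1 in turn had a rho of 0.47 with the mean of the slow-cycling and reserve list, at percentile 99.3, with 0.37 and 0.54 in the i7 groups and 0.31 outside that cluster, though -0.04 and 0.10 in clusters 2 and 3 against 0.53 and 0.55 in clusters 1 and 4. The median of the rhos of its members was 0.15, at percentile 95.9 and so inside the band, and lay outside it in 2 of 19 alternatives. The rho of Prox1 with the mean of the stem list was -0.14, but its sign was not stable. It was -0.17 and 0.21 in the i7 groups, 0.17 and -0.25 in the i5 groups, and 0.44, -0.48, 0.32 and 0.45 in clusters 1 to 4. Single genes of the regenerative list went apart with Prox1, with S100a6 at 0.51 and Ly6a at -0.34.

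Near-identical pairs of libraries were the first pattern weighed. Of 781 genes seen in exactly 2 libraries, 18.2% were seen in both libraries of such a pair, against 0.390% by chance, which falls short of the 20% set beforehand; that bound ignored that few libraries are paired. Among the 207 of these genes with a paired library the share was 68.6%, against 1.01% by chance. The pairs were picked for their high r, so a share above chance was likely from the start. It cannot separate cDNA of 1 cell in both libraries of a pair, which stays a candidate explanation, from 2 very similar cells. Argued against are reads assigned to a wrong index pair, since 2 of the 6 pairs share an index and 4 share none. Cells in a like state as the whole cause are argued against by the index, since all 8 libraries of N709 are paired, against at most 7 of any i7 index in 10000 random orders of the indexes, while the 26 other pairs of N709 libraries had a median r of only 0.631. Apart from cells in a like state, no biological explanation was tested.

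Low Defa24 in many libraries was the second pattern. It was above 0 in 100% of the 13 libraries that share an index with the defensin-high library and in 19% of the 42 others. Free RNA in the suspension would reach both kinds alike, which these shares argue against as the main cause. Reads assigned to a wrong index pair may account for the index-sharing libraries. Defa24 there ran from 18.8 to 596 TPM with a median of 40.1 TPM, so a uniform rate of such reads would not account for the highest value. The 8 libraries above 0 that share no index, with up to 278 TPM, are left unexplained. No biological explanation was tested.

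The fall of Prox1 with S phase genes was the third pattern. Spearman's rho was -0.44 after TPM were rescaled without ribosomal protein genes and Gm10925, and the partial rho given genes per cell was -0.49, both below the 2.5th percentile of random lists. The weakest of the 4 index groups gave -0.30. These values argue against ribosomal protein genes and Gm10925 in the TPM denominator, genes per cell and these 4 index groups as the whole cause. Other genes that take a large share of TPM were not removed, so their part in the denominator was not tested. Each group pooled several indexes and no single i7 index was left out, so differences between single i7 indexes are not covered. Such differences were present. Over its 8 libraries, N708 had the lowest median of Prox1 (3.5 TPM), the highest S phase median (4.02), and 6 libraries in cluster 1. N707 had the highest median of Prox1 (30.8 TPM), an S phase median of 1.19 and 0 libraries in cluster 1. N704, with the lowest S phase median (1.11), had Prox1 at only 12.2 TPM. A part of the i7 index in the relation therefore stays open. A difference between cycling and other cells may still be a property of these 3 tumors, and whether Prox1 varies with cycling itself or with another feature of the S phase-like cells stays open, so the relation stays a hypothesis.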
